A study of Homo sapiens with 4 samples.

How the data were processed

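RNA from 4 cultures of human mantle cell lymphoma lines was sequenced. The lines Mino and Z138 each carried either a doxycycline-inducible short hairpin against BTK or a control vector, and each culture had received doxycycline for 48 hours. There was 1 library per line and vector. RNA had been extracted with a column kit and libraries made with an Illumina TruSeq RNA kit, per the labels' protocols. Whether poly(A) selection was used is not given in the sources used here.

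The authors deposited 1 table of FPKM values (fragments normalized to transcript length and to the number of mapped fragments), with 1 column per library and 1 row for each of 25277 gene symbols, per the file headers. TopHat and the hg19 build are named in the submitters' processing notes, without versions. The program that turned alignments into FPKM, its annotation and its filters are not given in the sources used here. All 4 columns were used, each matched to its library by the line and vector in its heading.

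FPKM values are not counts, and the number of reads per library is unknown. The low values were searched for steps that would give relative depth. Among genes at or below 0.1 FPKM, the commonest ratio of the Mino control to the Mino hairpin value was 0.933, shared by 15.9% of 1227 low genes within 0.05 on the log2 scale. For the Mino control against the Z138 hairpin library it was 0.717, shared by 20.1% of 688 low genes. For the Z138 control library no ratio was shared by more than 6.52% of low genes. These ratios did not recover whole reads, so no counting interval is given.

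Of the 25277 symbols, 7627 were listed at 0 in all 4 libraries. Exact zeros in this table can be failed estimates: the tubulin gene TUBB was listed at 0 in all 4 libraries, and the elongation factor gene EEF1A1 was listed at 0 in the Z138 control and at 6404 to 6976 FPKM in the other 3 libraries. In 59 symbols, 1 member of a line's pair was listed at 0 while the other was at 5 FPKM or more, and 53 of these were small noncoding or microRNA genes. For genes listed at 0 only the values are given, with no fold change.

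Values were analysed as log2(FPKM + 1), a scale that understates the change of genes with low values. The across-line comparison was made with limma 3.58.1 in R 4.3.3 (linear model with cell line and hairpin as additive terms, moderated with a mean-variance trend). It used the 11484 symbols with a mean of at least 1 FPKM over the 4 libraries, and Benjamini-Hochberg adjusted p-values at 0.05. Each line supplied its own control, so the line was the block that paired the libraries. The model left 1 residual degree of freedom per gene, and its error is the difference in response between the lines. The 2 lines were the only replication, so p-values measure how alike 2 lines responded, not the spread between cultures of a line. The same model gave the comparison of Z138 with Mino.

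Within a line, genes were described by size alone (at least 2-fold), because a line had 1 library per group and no replicate. Concordance was counted at 1.5-fold in the same direction in both lines, beside the number that independent lists of the same lengths would share. In all, 32 gene lists were fixed before the data were examined. For each list with at least 5 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. A list stands apart here where it lay under 2.5% or over 97.5% of the random lists in both lines on the same side. BTK was left out of every list. Where members are said to pass adjusted over the list alone, p-values were adjusted within that list. That step was not part of the plan and was not corrected for the number of lists, so such calls are descriptive. Another 2 lists (heat shock proteins and aminoacyl-tRNA synthetases) were added after the data had been seen.

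GC content and transcript length came from the longest transcript of each symbol in GENCODE release 29 (GRCh38); 93.9% of the tested symbols had a value. That build also served to say which symbols lie in the MHC region, on chromosome 6 or in the pseudoautosomal regions; none of its coordinates are printed. A corrected set of ratios was made by removing, in each line, cubic spline trends of the log2 ratio on GC content and on log length, fitted with ratios limited to 1 either way.

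Named genes followed a rule fixed before the data were examined. It took BTK, BCL2 and FBXO10. For the hairpin in both lines it took the 10 strongest rises and the 10 strongest falls by the smaller of the 2 ratios at a mean of at least 5 FPKM, filled from genes that did not pass the test where fewer than 10 passed. It took the 5 strongest rises and falls in each line, the 5 strongest per orientation for opposite ratios, the 5 strongest per direction between the lines, and up to 4 members of each described list with ratios of the same sign in both lines. Unnamed loci, antisense RNAs, small RNAs and immunoglobulin variable segments were left out of the rule and only counted. Exceptions are these. Genes listed at 0 in a library used were passed over. A Y-linked symbol was left out, and some genes that the rule takes are not reported here. List members named for their ratio in a single line, HIST1H1E, IL4I1, the small RNAs and readthrough symbols that passed the test, and the genes of the closing section were chosen after their values had been seen.

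The limma model was tested on simulated data with 200 genes, changed alike in both lines, among the 11150 above 0 in every library. It recovered 0% of genes changed 1.5-fold, 96.5% of those changed 2-fold and 98.5% of those changed 4-fold. The reported test also held genes with zeros and had fewer prior degrees of freedom (6.88, against 18.88 without those genes), and genes whose ratios differ between the lines carry a larger error, so these shares do not apply to it as they stand. The alternatives were a model without the line block, rescaling by the upper quartile, no filter, a filter at 5 FPKM, limma without the trend, a pseudocount of 0.1, and each line alone. Removal of genes listed at 0 in any library and the GC and length correction were added after the data had been seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and patsy 1.0.2 was used for the rest, and matplotlib 3.10.9 for the plots. No batch, date or lane labels were given, so batches could not be examined.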

Results

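Mantle cell lymphoma is a B cell cancer, and Mino and Z138 are established cell lines derived from it. Gene expression was measured by RNA sequencing after knockdown of BTK, the kinase that passes signals from the B cell receptor to NF-kB and other pathways. The series concerns BTK, the ubiquitin ligase subunit FBXO10 and the anti-apoptotic protein BCL2. In each line, a culture expressing an inducible hairpin against BTK was set against a culture with a control vector, 48 hours after doxycycline. The labels do not say what the control vector expressed. There was 1 hairpin culture per line and no culture labelled with another hairpin was analysed here, so effects of the hairpin on genes other than its target cannot be separated from those of BTK loss. There were 4 libraries, 1 per line and vector. Read depth is unknown. The 4 columns summed to 669475 FPKM in the Mino control, 669013 in the Mino hairpin, 740192 in the Z138 control and 712326 in the Z138 hairpin library. Between 14953 and 16007 symbols were above 0 in a library, and ribosomal protein genes made up 38.5% to 45.7% of the summed FPKM.

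BTK was examined first, as the target of the hairpin. It was at 37.0 FPKM in the Mino control and 9.84 in the Mino hairpin library, and at 51.0 in the Z138 control and 12.4 in the Z138 hairpin library. The hairpin libraries thus held 26.6% and 24.3% of the control value. Across both lines BTK fell by 1.88 on the log2 scale (SE 0.13, adjusted p = 0.000964 in limma, lower in 2 of 2 lines). The 8 measured neighbours of BTK on the X chromosome had median log2 ratios of 0.01 in Mino and −0.01 in Z138. BTK alone passed the test after the GC and length correction without genes listed at 0, but it did not pass without the line block or without the filter on low values.

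BCL2 and FBXO10, the other 2 genes in the question, did not pass the test. BCL2 was at 491 FPKM in the Mino control and 297 in the Mino hairpin library, a log2 ratio of −0.72. In Z138 it was at 61.2 and 54.0, a log2 ratio of −0.18. The mean over both lines was −0.45 (SE 0.15, adjusted p = 1.00 in limma, lower in 2 of 2 lines). FBXO10 was at 17.4 and 14.8 FPKM in Mino and at 3.36 and 3.15 in Z138, with a mean log2 ratio of −0.14 (SE 0.14). In simulated data on 11150 genes above 0 in every library, 0 of 200 genes changed 1.5-fold were called. The reported test holds more genes and was not simulated, so a change of that size cannot be ruled out.

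**Figure D1:**
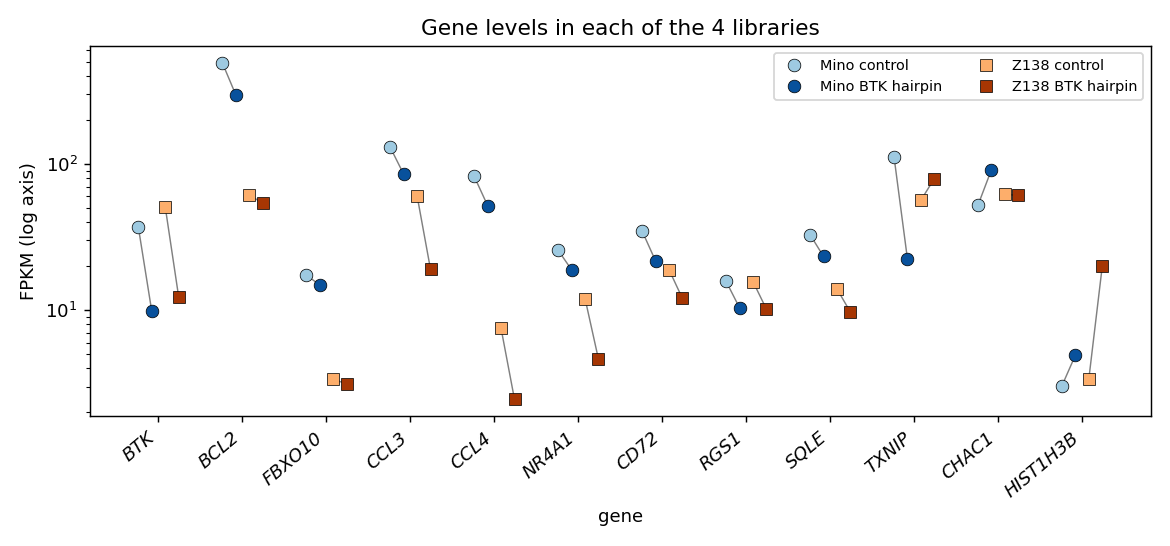
FPKM on a log axis of 12 genes in each of the 4 libraries, with circles for Mino, squares for Z138, pale symbols for control and dark symbols for hairpin libraries; grey lines join the libraries of a line. BTK drops from 37.0 to 9.84 in Mino and from 51.0 to 12.4 in Z138, while TXNIP stands at 111 and 22.2 in Mino and at 56.4 and 79.4 in Z138.

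The first comparison asked which genes differed between hairpin and control in the same way in both lines. Besides BTK, the RNA components of RNase MRP (RMRP) and RNase P (RPPH1) rose. Both are small noncoding RNAs, and the 33 measured members of that list above 0 in every library had median log2 ratios of 0.58 in Mino and 0.32 in Z138. RMRP was at 143 and 329 FPKM in the Mino control and hairpin libraries and at 55.5 and 189 in Z138, a mean log2 ratio of 1.47 (SE 0.15, adjusted p = 0.0142 in limma). RPPH1 was at 46.6 and 116 FPKM in Mino and at 13.5 and 71.4 in Z138, a mean log2 ratio of 1.81 (SE 0.22, adjusted p = 0.0364). The linker histone gene HIST1H1E rose from 0.913 to 2.99 FPKM in Mino and from 1.51 to 5.61 in Z138 (mean log2 ratio 1.23, SE 0.15, adjusted p = 0.0364). With the GC and length correction these 3 genes did not pass in limma (adjusted p = 0.378, 0.56 and 0.347), although their ratios were 1.37 (SE 0.16), 1.74 (SE 0.25) and 1.25 (SE 0.14). The prior degrees of freedom shared across genes were 6.88 before the correction and 3.96 after it. In total 14 of 11484 symbols passed in limma, 7 higher and 7 lower in the hairpin libraries, and 320 had an unadjusted p under 0.05. These 320 are a smaller share of the symbols than the 0.05 that a test with no true change would give.

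Of the 14, 9 were small noncoding RNAs, 2 were histone genes and 3 were others. A value of 0 in at least 1 library lay behind 8 of the 14, among them SNORA41, which was at 57.5 and 78.2 FPKM in the Mino and Z138 controls and listed at 0 in both hairpin libraries. SNORA43 was listed at 0 in both controls and at 110 and 17.1 FPKM in the hairpin libraries. The readthrough symbols TMEM256-PLSCR3 and ABHD14A-ACY1 also passed. They overlap the single genes they join, so their values are uncertain, and histone and small RNA genes have near-identical copies that can share reads. Without the 334 tested symbols listed at 0 in any library, a step chosen after the data had been seen, 28 symbols passed, and with the GC and length correction 6 passed.

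The other genes in the ranking of lower genes did not pass the threshold over all genes. CCL3 and CCL4, chemokines released by B cells on receptor stimulation, were at 130 and 82.1 FPKM in the Mino control and at 85.0 and 51.8 in the Mino hairpin library. In Z138, CCL3 was at 60.4 and 19.0 FPKM and CCL4 at 7.49 and 2.45. Their mean log2 ratios were −1.11 (SE 0.22, adjusted p = 0.361 in limma) and −0.98 (SE 0.17, adjusted p = 0.226). Without symbols listed at 0 both passed in limma (adjusted p = 0.00221 and 0.00302), as did the nuclear receptor gene NR4A1 (adjusted p = 0.038) and the amino acid oxidase gene IL4I1 (adjusted p = 0.0472). The ratios of CCL3 and CCL4 were unchanged in that setting, and their SE were 0.17 and 0.16. Its prior degrees of freedom were 18.88, against 6.88 with all tested symbols, so the smaller p-values do not come from larger changes. With the GC and length correction none of these 4 passed, with ratios about as large: −1.10 (SE 0.24) for CCL3, −0.98 (SE 0.17) for CCL4, −0.78 (SE 0.18) for NR4A1 and −0.64 (SE 0.17) for IL4I1, beside −0.82 for NR4A1 and −0.69 for IL4I1 before it. CD72, a B cell co-receptor, had log2 ratios of −0.65 in Mino and −0.61 in Z138. RGS1, a regulator of chemokine receptor signalling, had −0.56 and −0.58, and the Fc receptor-like gene FCRL5 −0.44 and −0.60. SQLE, a cholesterol pathway gene, had −0.48 and −0.48. PFKFB4, a regulator of glycolysis, had −0.48 and −0.48, and SMIM4 −0.65 and −0.47. On the other side stood HIST1H4H (0.77 and 1.31), HIST1H3B (0.55 and 2.26), LGALS3BP (0.48 and 0.40), C1orf54 (0.66 and 0.40), GPR18 (0.40 and 0.37), DEPTOR (0.43 and 0.36), SBDSP1 (0.36 and 0.36) and MCEE (0.36 and 0.35).

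**Figure D2:**
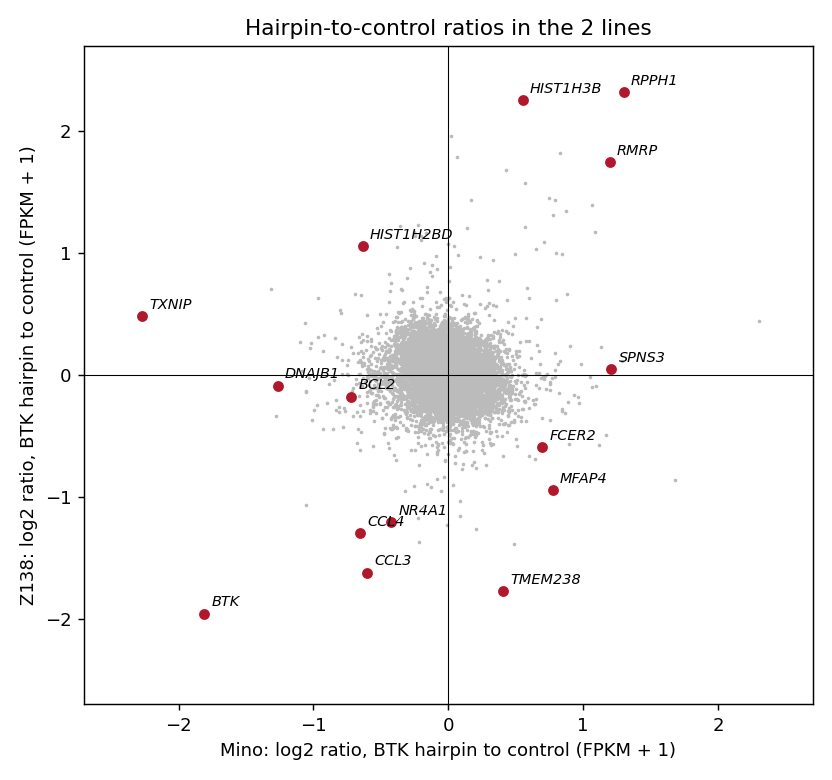
Log2 ratio of hairpin to control in Mino (x axis) against Z138 (y axis), on FPKM + 1, for the 11150 tested genes above 0 in every library; grey points are genes, red points are 15 named genes, and 1 gene lies outside the axes. BTK lies at −1.81 and −1.96, and RPPH1 at 1.30 and 2.32, while TXNIP, at −2.27 in Mino and 0.49 in Z138, lies far from the diagonal.

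Concordance of the 2 lines was then examined. At 1.5-fold, 21 genes were higher and 11 lower in both hairpin libraries, against 1.00 and 1.16 that independent lists of those lengths would share. In opposite directions 21 genes differed at 1.5-fold, against 2.20. Without genes listed at 0 there were 16 higher and 5 lower in both, and 11 in opposite directions. Over all 11484 genes the log2 ratios of the 2 lines had a Spearman rho of −0.17 and a Pearson r of −0.04. Within 10 bins of expression, rho ran from −0.25 to −0.07. These are relations across genes, which are not independent replicates. The 2 ratios share no library. In Z138 the ratio went down with GC content (rho −0.57 across 10477 genes above 0 in every library) and in Mino it went slightly up (rho 0.11). With that trend and the length trend removed, rho between the lines was −0.11.

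**Figure D3:**
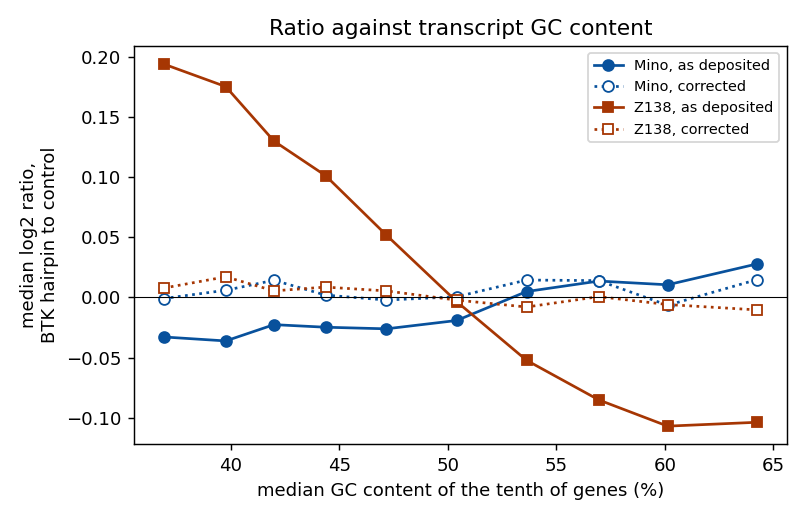
Median log2 ratio of hairpin to control (y axis) in 10 equal bins of genes by transcript GC content in percent (x axis), for Mino (circles) and Z138 (squares), as deposited (filled, solid lines) and after the GC and length correction (open, dotted lines). The Z138 medians run from 0.19 in the bin of lowest GC content to −0.10 in the bin of highest, and the Mino medians from −0.03 to 0.03.

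Of the lists fixed before the data were examined, 25 had at least 5 measured members, and 3 stood apart in both lines, all on the lower side. Taken line by line, 15 of the 25 lay outside the range of random lists in Mino and 5 in Z138, so lying outside it in 1 line was common. Random lists draw unrelated genes, whereas members of a list can vary together, so these percentiles are not tests. Genes of cholesterol synthesis had a median log2 ratio of −0.26 in Mino and −0.28 in Z138, each below all 10000 random lists, with 15 of 17 members below 0 in Mino and 17 of 17 in Z138. No member passed over all genes; adjusted over the list alone, 3 passed as lower in limma, SQLE and INSIG1 among them. INSIG1, which holds the sterol sensor in the endoplasmic reticulum, had log2 ratios of −0.68 in Mino and −0.30 in Z138. FDFT1, the squalene synthase gene, was at 154 and 121 FPKM in Mino and at 30.0 and 24.5 in Z138. After the GC and length correction the medians were −0.25 and −0.27.

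Genes of hypoxia and glycolysis had medians of −0.47 in Mino, below all random lists, and −0.15 in Z138, at the 0.05 percentile. In Mino 19 of 20 members were below 0, and in Z138 14 of 20. None passed over all genes, and 0 passed adjusted over the list alone in limma. The glycolytic enzyme gene ENO1 had log2 ratios of −0.38 in Mino and −0.27 in Z138. ALDOC, another glycolytic enzyme gene, was at 249 and 166 FPKM in Mino and at 36.0 and 29.3 in Z138. ANKRD37, a hypoxia-induced gene, had log2 ratios of −0.78 and −0.43.

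Early response genes, which switch on within the first hour of receptor stimulation, had medians of −0.43 in Mino, below all random lists, and −0.18 in Z138, at the 0.03 percentile. In Mino 13 of 14 members were below 0, and in Z138 9 of 14. None passed over all genes. Adjusted over the list alone, 4 passed as lower in limma, namely NR4A1, EGR3, DUSP2 and FOS. Over all genes the adjusted p of these 4 was 0.703 or more in limma. NR4A1 had log2 ratios of −0.43 in Mino and −1.21 in Z138. DUSP2, a phosphatase of MAP kinases, was at 72.5 and 53.4 FPKM in Mino and at 50.8 and 37.3 in Z138. In Z138 the list's place was not kept: among the 9 members with a mean of at least 5 FPKM its median was 0.11, at the 90.8 percentile, and after the GC and length correction it was −0.08, at the 3.6 percentile.

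**Figure D4:**
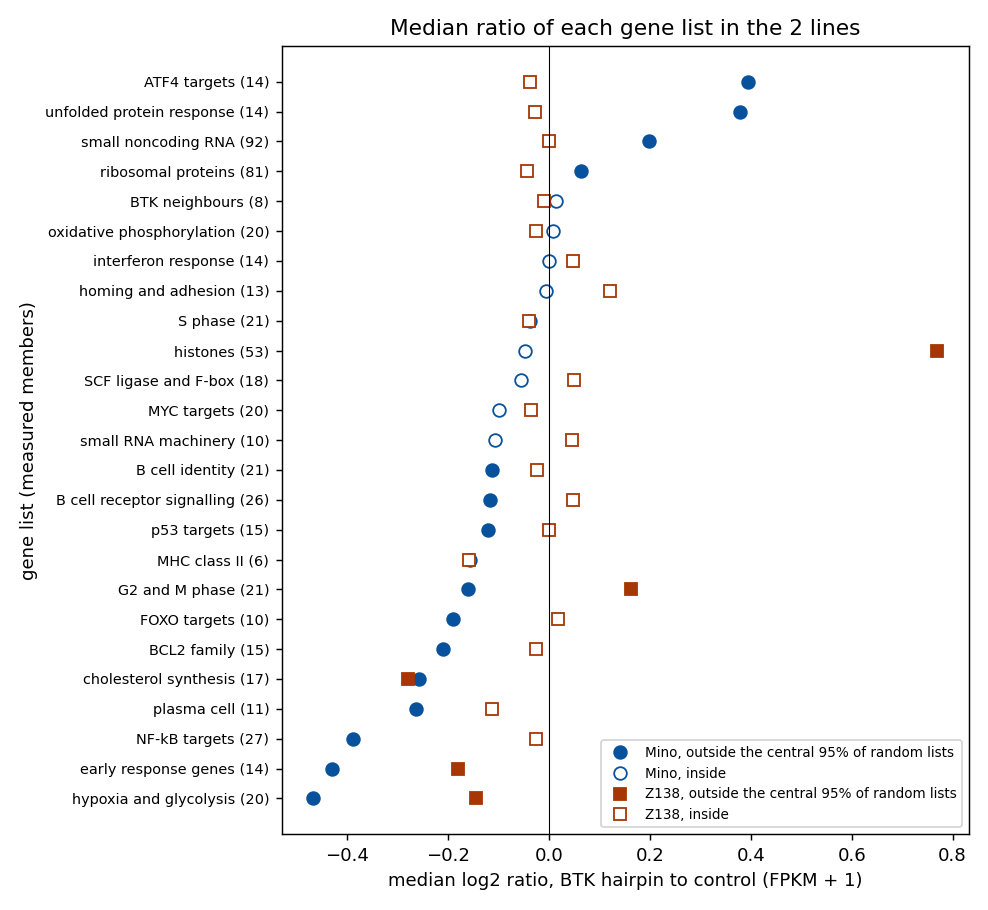
Median log2 ratio of hairpin to control (x axis, FPKM + 1) of each of the 25 gene lists (y axis, measured members in brackets) in Mino (circles) and Z138 (squares); filled symbols lie outside the central 95% of 10000 random lists. Cholesterol synthesis, early response genes, and hypoxia and glycolysis are filled on the lower side in both lines, whereas ATF4 targets lie at 0.40 in Mino and −0.04 in Z138.

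Within Mino, ATF4 targets and unfolded protein response genes stood on the higher side and NF-kB targets on the lower side, and none of them passed the test across lines. ATF4 targets, which serve amino acid supply and the integrated stress response, had a median log2 ratio of 0.40, above all random lists, with 14 of 14 members above 0. CHAC1 was at 52.3 and 91.2 FPKM, TRIB3 at 141 and 239, and PSAT1 at 39.8 and 66.7. The unfolded protein response list had a median of 0.38, with 14 of 14 members above 0, among them SDF2L1 (25.5 and 45.8 FPKM), XBP1 (98.4 and 160) and HSPA5 (91.5 and 131). NF-kB targets had a median of −0.39, below all random lists, with 25 of 27 members below 0. EBI3 was at 38.5 and 22.9 FPKM and NFKBIE at 46.2 and 31.0; adjusted over the list alone, CCL3 and CCL4 passed as lower in limma. In Z138 these 3 lists had medians of −0.04, −0.03 and −0.03, all inside the range of random lists. The difference between the lines was not tested, since each line had 1 pair of libraries.

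The BCL2 family list had a median of −0.21 in Mino, at the 0.02 percentile, with 13 of 15 members below 0, and −0.03 in Z138, at the 33.6 percentile. Its members BID (32.9 and 22.6 FPKM), BCL2A1 (15.8 and 11.1) and BCL2L11 (87.1 and 65.3) were lower in the Mino hairpin library along with BCL2, and BCL2L1 was at 42.0 and 38.7 FPKM in Mino and at 32.6 and 24.7 in Z138. B cell receptor signalling genes had a median of −0.12 in Mino, at the 0.48 percentile, and 0.05 in Z138. Plasma cell genes had medians of −0.26 and −0.11, FOXO targets −0.19 and 0.02, p53 targets −0.12 and −0.00, B cell identity genes −0.11 and −0.02, and ribosomal protein genes 0.06 and −0.04, each outside the range of random lists in Mino and inside it in Z138. Of these, B cell identity lay inside the range in Mino after the correction (median −0.02). Plasma cell genes lay below the range in both lines after the correction (medians −0.16 and −0.19, at the 1.06 and 0.15 percentiles) and at 5 FPKM or more (−0.17 and −0.19, at the 1.05 and 0.58 percentiles). Each of these settings held 10 members. As deposited, only 2 of the 11 plasma cell members were below 0 in both lines and 0 were above 0 in both. The low medians thus came mostly from different members in each line, not from a shared fall. Adjusted over the list alone, CD72 passed in the B cell identity list and RGS1 in the homing and adhesion list. By size alone, 74 genes differed at least 2-fold in Mino, 39 higher and 35 lower, and 44 of them were small noncoding RNAs. Among genes with a mean of at least 5 FPKM in the line, small RNAs aside, the highest ratios besides RPPH1 and RMRP belonged to SPNS3 (17.7 and 42.1 FPKM), SLC12A8 (4.97 and 11.7) and, just under 2-fold on this scale, C4orf48 (6.83 and 14.3, log2 ratio 0.97). The lowest ratios among them belonged to TXNIP (111 and 22.2), BTK, IGFBP2 (16.8 and 6.34), DNAJB1 (197 and 81.5) and TNNI2 (28.5 and 12.8). Without genes listed at 0, 30 genes differed 2-fold in Mino.

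Within Z138, histone genes were higher in the hairpin library. The list of 53 measured histone genes had a median log2 ratio of 0.77, above all random lists, with 46 of 53 members above 0, whereas in Mino its median was −0.05 with 25 of 53 above 0. Among members with a mean of at least 5 FPKM the Z138 median was 0.23. The Z138 control library itself stood apart from the other 3 in having no common step among its low values, and the Z138 ratios followed GC content (rho −0.57). EEF1A1 was listed at 0 in that library alone, but PPIE was likewise listed at 0 in the Mino control alone. After the GC and length correction the histone median in Z138 was 0.75, above all random lists. HIST1H3B was at 3.40 and 20.0 FPKM, HIST1H4H at 3.86 and 11.1 and HIST1H3H at 4.50 and 11.8. Across both lines 2 histone genes passed over all genes and 14 passed adjusted over the list alone, all higher. Small noncoding RNAs had medians of 0.20 in Mino and 0.00 in Z138 over 92 measured members. Among these, 59 had a 0 in at least 1 library; over the other 33 the medians were 0.58 and 0.32, both above all random lists. With the GC and length correction the medians were −0.14 and −0.24, below all random lists, and over the 33 members they were 0.30 and 0.04, at the 100 and 97.96 percentiles. The correction was fitted on genes that include these 33, so its length term can take up part of their own shift. By size alone 90 genes differed at least 2-fold in Z138, 46 higher and 44 lower, of which 20 were histone genes and 47 small noncoding RNAs. Among genes with a mean of at least 5 FPKM in the line, small RNAs aside, the lowest ratios belonged to BTK, TMEM238 (8.69 and 1.84 FPKM), CCL3, FAM131C (8.35 and 2.89) and NR4A1. Without genes listed at 0, 44 genes differed 2-fold in Z138.

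Apart from the G2 and M phase list, which is given in the next paragraph, the remaining lists lay inside the range of random lists in both lines as deposited. After the GC and length correction, MYC targets lay below it in Mino (2.08 percentile), MHC class II genes below it in Z138 (0.13 percentile) and homing and adhesion genes above it in Z138 (99.74 percentile). Without genes listed at 0, MHC class II genes and MYC targets lay below it in Mino (1.67 and 2.44 percentiles). Their medians in Mino and Z138 were −0.04 and −0.04 for S phase, −0.06 and 0.05 for SCF ligase and F-box genes, −0.10 and −0.04 for MYC targets, 0.00 and 0.05 for interferon response, −0.01 and 0.12 for homing and adhesion, −0.11 and 0.05 for small RNA machinery, and 0.01 and −0.03 for oxidative phosphorylation. MHC class II genes had −0.16 and −0.16 over 6 measured members of 12. Lists of mantle cell markers, other TEC family kinases, and markers of T cells, myeloid cells, epithelium, fibroblasts and erythroid cells had fewer than 5 members at a mean of 1 FPKM or more, and no median is given.

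Some genes had ratios of opposite sign in the 2 lines. Higher in the Mino and lower in the Z138 hairpin library were MFAP4 (log2 ratios 0.78 and −0.94), PILRB (0.64 and −0.69), the low-affinity IgE receptor gene FCER2 (0.70 and −0.59), ACY3 (0.43 and −0.47) and KRTCAP2 (0.42 and −0.40). Lower in Mino and higher in Z138 were FAM65B (−0.69 and 0.67), HIST1H2BD (−0.64 and 1.06), HIST1H2BN (−0.97 and 0.64), KLF10 (−0.80 and 0.54) and HIST2H2AC (−0.51 and 0.50). The G2 and M phase list was also split, with a median of −0.16 in Mino, at the 0.06 percentile, and 0.16 in Z138, at the 99.99 percentile. After the GC and length correction these were −0.16 and 0.09, at the 0.05 and 99.81 percentiles. MKI67, the Ki-67 proliferation antigen gene, was at 27.0 and 19.3 FPKM in Mino and at 16.4 and 18.9 in Z138.

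The lines themselves differed far more than hairpin and control. In limma, 7745 of 11484 symbols passed for Z138 against Mino, 3293 higher in Z138 and 4452 higher in Mino. BCL2 was higher in Mino, with a log2 difference of −2.71 for Z138 minus Mino (SE 0.15, adjusted p = 2.25e-06 in limma), and so was FBXO10 (−2.01, SE 0.14, adjusted p = 6.66e-06). BTK was slightly higher in Z138 (0.38, SE 0.13, adjusted p = 0.0294). The genes furthest on the Z138 side were the immunoglobulin joining chain gene IGJ (log2 difference 8.82), CCND1 (7.26), the surrogate light chain gene IGLL1 (6.92) and the Wnt antagonist gene SFRP5 (6.67). CCND1, the cyclin gene placed next to an immunoglobulin enhancer by the translocation typical of this lymphoma, was at 3.18 and 2.62 FPKM in the Mino control and hairpin libraries and at 591 and 600 in Z138. Whether so low a level is usual for Mino cells was not examined here. On the Mino side were the AKT co-activator gene TCL1A (−7.90), the focal adhesion gene ZYX (−6.53), the glycophorin gene GYPC (−6.53), the hyaluronan receptor gene CD44 (−6.40) and CPXM1 (−6.37). TCL1A was at 673 and 502 FPKM in Mino and at 1.84 and 1.10 in Z138. Each line had 1 culture per vector, so line and culture were not separated.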

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

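The tests of explanations in this part were chosen after the results had been seen. Named genes and lists with ratios of opposite sign in the 2 lines are given here with the Z138 ratio minus the Mino ratio, for genes at least 1.5-fold either way in both lines. The differences were not tested, since each line had 1 pair of libraries. MFAP4 differed by −1.72 on the log2 scale (0.78 in Mino, −0.94 in Z138), PILRB by −1.33 (0.64 and −0.69) and FCER2 by −1.29 (0.70 and −0.59). In the other direction, FAM65B differed by 1.36 (−0.69 in Mino, 0.67 in Z138), HIST1H2BD by 1.69 (−0.64 and 1.06) and HIST1H2BN by 1.60 (−0.97 and 0.64). The G2 and M phase list differed by 0.32 (−0.16 and 0.16).

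HIST1H2BD and HIST1H2BN belong to a wider difference. Over 43 histone genes with a HIST symbol, above 0 in every library, the median log2 ratio was 0.89 in Z138 (95% bootstrap interval over genes 0.64 to 1.08) and −0.08 in Mino (−0.20 to 0.07). The size depends on genes with low values: the whole histone list had a Z138 median of 0.77, but 0.23 among members with a mean of at least 5 FPKM. The bootstrap intervals are over genes of 1 pair of libraries and do not measure the spread between libraries. In Mino the medians of 2 histone classes lay on opposite sides of 0, with overlapping intervals, and their difference was not tested. There H3 and H4 genes had a median of 0.25 (interval −0.10 to 0.66, 11 of 16 above 0), and H2A and H2B genes −0.14 (−0.25 to −0.05, 7 of 23 above 0). In Z138 the medians of these classes were 1.225 and 0.64. A larger share of cells in S phase was looked for in Z138. The S phase list had a median of −0.039 (interval −0.11 to 0.04), below the 0.2 that was asked of it once the values had been seen. The G2 and M phase list was higher there (median 0.16, at the 99.99 percentile), so these lists do not settle whether the cell cycle shifted. For the histones the GC and length trend is argued against, since their Z138 median was 0.85 after the correction (interval 0.56 to 1.00). Most replication-dependent histone transcripts lack a poly(A) tail, but whether each of these 43 does was not examined. A different share of RNA without a tail in the 2 Z138 libraries, more in the hairpin or less in the control library, is a candidate explanation. Small noncoding RNAs had a Z138 median of 0.32, with an interval of −0.01 to 0.50 that includes 0, so this explanation stays open. In Mino their median was 0.58 (interval 0.24 to 0.80, 27 of 33 above 0), where the histones as a whole did not rise. Their Z138 median was 0.04 after the correction, but the correction was fitted on genes that include them. Its length term can take up their own shift, so that value does not bear on the explanation. With 1 library per group the explanation cannot be told apart from a change in histone transcription or decay, or from a response of Z138 to BTK knockdown. The Z138 control library differed from the other 3 in having no common step among its low values. EEF1A1 was listed at 0 in it alone, but PPIE was likewise listed at 0 in the Mino control alone, so such a zero does not mark out 1 library.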

How the results depend on the processing

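The 14 genes of the across-line test became 0 with no replicate block (cell line left out of the model; 9 had an unadjusted p under 0.05 in limma), 2 with no filter on low values and 9 with a filter at 5 FPKM. They became 28 without genes listed at 0, 6 with the GC and length correction and 1 with both. These last 3 alternatives were chosen after seeing the data. Leaving out the block puts the difference between the lines into the error. Of the 14 genes, 9 were shared with the filter at 5 FPKM, 6 with the call without zeros and 6 with the corrected call. For the other changes the cause was not tested. BTK had the same ratio, −1.88, without the block and without the filter but did not pass there (adjusted p = 1.00 and 0.101 in limma, against 0.000141 to 0.0159 under 6 other alternatives and 1.47e-07 without zeros). Either line alone gave −1.81 or −1.96. Genes 2-fold apart in Mino were 46 at 5 FPKM, 131 with a pseudocount of 0.1, 30 without zeros and 248 at 1.5-fold; in Z138 they were 55, 154, 44 and 202. The filter and the removal of zeros leave fewer genes, and a smaller pseudocount widens ratios of low genes. Genes 1.5-fold apart in the same direction in both lines were 16 at 5 FPKM, 61 with a pseudocount of 0.1, 21 without zeros, 19 with the correction as well, and 15 at 2-fold. The number of lists apart in both lines was 3 or 4, but early response genes were not among them at 5 FPKM, where their Z138 median reversed to 0.11, or after the correction. The small noncoding RNA median in Mino reversed to −0.14 with the correction. The cause was not tested for either. No result reversed in rescaling by the upper quartile. Over the other 370 comparisons of named genes, list medians and the correlation between lines, 332 kept their side of the threshold or, where no test applied, moved by at most 25%, and 30 untested values moved more, all in the same direction. A tested gene far from the threshold keeps its side even if its size changes, so the 332 do not measure stability of size. DEPTOR was counted as kept although its mean log2 ratio went from 0.40 to 0.77 with a pseudocount of 0.1. Without zeros, CCL3, CCL4, HIST1H3B and HIST1H4H of the genes in this count passed that had not (22 of all 28 calls were not among the 14), with the correction RPPH1 and RMRP lost their call, and 2 medians reversed, as given. Either line alone gave −0.18 or −0.72 for BCL2 and −0.60 or −1.62 for CCL3. Depth is unknown, so a precision for low values could not be set.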

Other observations

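The test of symbols with several positions was set before its result was seen; the other tests in this part were chosen afterwards. Heat shock protein genes, a list added after the data had been seen, were lower in the Mino hairpin library: all 19 measured members had negative ratios, with a median log2 ratio of −0.46, below all 10000 random lists. DNAJB1 was at 197 and 81.5 FPKM in the control and hairpin libraries, HSPA8 at 432 and 249, SERPINH1 at 101 and 59.0 and HSPH1 at 66.3 and 37.9. In Z138 the median was 0.13, at the 99.85 percentile, with 7 of 19 members negative, and after the GC and length correction it was 0.04. Aminoacyl-tRNA synthetase genes, the other added list, had medians of 0.18 in Mino and 0.10 in Z138, at the 99.99 and 99.67 percentiles, and 0.05 in Z138 after the correction.

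Of the D-type cyclin genes, CCND1 was at 591 FPKM in the Z138 control and 3.18 in the Mino control, CCND3 at 15.3 and 28.4, and CCND2 under 0.01 in every library. SOX11, a transcription factor gene typical of mantle cell lymphoma, was at 23.6 FPKM in the Mino control and 19.8 in the Z138 control. CDKN2A was at 30.3 and 31.4 FPKM in the Mino libraries and listed at 0 in both Z138 libraries. Of 7 epithelial markers, 3 had a mean of 1 FPKM or more over the 4 libraries, with their values in Mino: KRT8 was at 25.5 and 22.5 FPKM, EPCAM at 7.29 and 7.56 and KRT18 at 6.07 and 6.13, against 0.396 or less in Z138. In Mino CDH1 was at 1.07 and 0.488 FPKM and KRT5 at 0.611 and 0.180, and KRT19 and KRT14 were listed at 0 in all 4 libraries. The highest T cell, myeloid, fibroblast and erythroid marker in any library was at 3.95 (ZAP70), 4.03 (CD68), 4.55 (COL1A1) and 0.409 FPKM (HBA2). TEC, a kinase gene related to BTK, was at 3.16 and 2.10 FPKM in the Z138 control and hairpin libraries and under 0.04 in Mino.

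Of 147 protein-coding symbols in the MHC region of chromosome 6, taken by neighbourhood from GRCh38, 126 were listed at 0 in all 4 libraries (85.7%), against 22.2% on the rest of that chromosome and 19.1% on the others. Of 10 genes chosen as widely used, among them TUBB, RPS18, VARS and BAG6, 9 were listed at 0 in all 4, and the other symbol was not in the table. With 126 of 147 symbols at 0, this count could hardly have come out otherwise. Silence of the region is thus argued against only by the wide use of these genes, not by the count. The hg19 build carries extra haplotypes of this region. If symbols placed at 2 or more positions of hg19 get no value, genes shared by X and Y should also be listed at 0, and 100% of 18 pseudoautosomal symbols were. This is consistent with a loss in the authors' processing as a candidate explanation. It bears on the NF-kB list, where TNF, LTA and IER3 are among the symbols at 0, and on 5 of the 12 MHC class II symbols.

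In the Mino hairpin library ATF4 targets and unfolded protein response genes were higher while NF-kB targets were lower. The GC and length trend is argued against by its size in Mino. Median ratios there were −0.03 in the lowest and 0.03 in the highest GC bin, and −0.10 in the tenth of longest transcripts. The correction could thus move list medians little. The ATF4 median was 0.40 after it (95% bootstrap interval over genes 0.24 to 0.62), beside 0.40 before it. Medians of the unfolded protein response and NF-kB lists were 0.37 and −0.35 after it, beside 0.38 and −0.39. TXNIP and ARRDC4, genes that respond to glucose supply, had log2 ratios of −2.27 and −1.06 in Mino, at 20.0% and 19.8% of the control FPKM, and 0.49 and 0.43 in Z138. A difference between the Mino cultures in nutrients or density is a candidate explanation, but no value examined here measures either. With 1 library per group the ratios of TXNIP and ARRDC4 cannot be told apart from an effect of the hairpin. A response to BTK knockdown that differs between the lines is the biological hypothesis, and the ATF4 medians differed by −0.43 (Z138 minus Mino). With no replicate culture it stays open.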
